A study of Mus musculus with 2 samples.

How the data were processed

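H3K27me3 ChIP-seq was done on stomach from embryos of 14.5 days, with 2 biological replicates of 1 group, per the labels. Replicate 1 combined technical replicates 1 and 2, replicate 2 had technical replicate 1, and fragments were selected at 300 to 500 bp, per the labels. The sexes were pooled in each sample. No group was compared with another, since the series holds 1 group.

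The authors deposited 4 peak lists in the narrowPeak layout on assembly mm10, per the file headers and the text files that accompany the samples. Peaks were called on each replicate, and on both pooled; the replicated list was derived from those 3 lists, per the accompanying text. Replicate 1 and the pooled list were derived with 2 control alignment files and replicate 2 with 1, per the same text, so the controls differed between the replicates. The aligner, the peak caller and their versions were not given in the sources used here. Each peak has a fold enrichment over control as a linear ratio, a −log10 p-value and a −log10 q-value, all the authors' own deposited values, used only to describe, rank or filter peaks within a list. From the values, no peak had a −log10 p-value below 2.02, 2.10, 2.05 or 2.05 in the pooled, replicate 1, replicate 2 and replicated lists, and q-values reached 1 in all but the replicate 1 list, so the authors' deposited lists follow a p-value threshold without one on q. At a q-value of 0.05, 54.6% of replicate 1 peaks, 52.3% of replicate 2 peaks, 70.6% of pooled and 92.0% of replicated peaks remained. A narrow-peak layout divides broad marks into many pieces, and a threshold on p lets the number of peaks move with depth, so counts of peaks were not compared as amounts of the mark. Depth per library was unknown: the lists hold no read counts, and intervals (95%, Wilson) cover the counting of peaks only.

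Coordinates were compared with GRCm38 patch 6 and GENCODE mouse release M21, the same build as mm10. In the 4 lists 0 peaks ran past a chromosome end and 0 lay in assembly gaps, and 1 replicate 1 peak on an unplaced scaffold was left out of counts by chromosome. A gene was called marked if any annotated transcription start of a protein-coding gene had at least 1 base of a replicated peak within 1 kb to either side (93513 starts, 21938 genes). Of these genes 54 share a symbol with another. Peaks were assigned to promoter, exon, intron or intergenic sequence in that order. Overlap meant at least 1 shared base, domains joined peaks with gaps of at most 3 kb, and chance levels came from 100 shuffles within chromosomes with bedtools 2.31.1. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

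The 41 gene lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined. Each list was tested by a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over 41 lists and a threshold of 0.05. Log2 ratios of observed to expected marked genes used a pseudocount of 0.5. Genes are not independent replicates, and these p-values describe the list of marked genes, not variation between embryos. Families given by symbol pattern (such as Zfp) hold whatever genes carry that symbol. Named were 20 genes fixed in advance, up to 4 marked members per list with the most bases covered within 2.5 kb of a start and up to 3 unmarked members in alphabetical order, and genes of the 15 longest domains. Members of counts of 5 or fewer, the remaining unmarked Hox genes, Hoxb6, Hoxb7, St18, Isl1 and Hand2 were named after their values were seen.

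Alternatives were windows of 500 bp and 2.5 kb, at least 500 covered bases, the 5'-most start only, a q-value of at most 1e-05, the pooled list, each replicate alone, genes matched by CpG decile (10000 draws), 1 gene per cluster (100 kb), a background without receptor genes, other overlap rules and domain gaps of 1 and 10 kb. Added after the data were seen were a q-value of at most 0.05, promoters marked in both replicates' own lists, and autosomes only. On simulated data 200 of 200 planted promoter peaks were recovered. Over 100 random markings of 21938 genes, 1 gave any list call. With 50% of the members of 8 lists marked, 93.5% of 200 list tests were called. Lower shares were not simulated. The random markings were drawn evenly over genes, without dependence on CpG content and without peaks shared by neighbouring genes. They therefore do not give the rate of false calls in the real lists. The simulation covered the comparison of gene lists among marked promoters and no other comparison.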

Results

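Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark that Polycomb repressive complex 2 places on silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing in mouse stomach at embryonic day 14.5. Both libraries belonged to 1 group, stomachs pooled from male and female embryos of the B6NTac;B6NCrl background. Per the labels the 2 libraries were biological replicates from separate pooled samples; replicate 1 combined 2 technical replicates and replicate 2 had 1. No other tissue, age or treatment was part of the series, so the comparisons below were between replicates, between peak lists and between groups of genes within this tissue. The authors' lists held 35297 peaks for replicate 1, 11818 for replicate 2, 22931 for both replicates pooled and 11612 replicated peaks. These covered 12.8, 4.30, 11.9 and 8.85 Mb of the mm10 genome, with median widths of 257, 280, 321 and 543 bp. Read counts per library were not given in the sources used here, so depth is unknown and the intervals below cover counting error only.

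Sox2, which specifies the foregut and stomach epithelium, carried the mark at its promoter, and so did Gata4, Gata6 and Foxa2. Per the labels the libraries came from stomach tissue, so the peaks do not show which of its cell types carried the mark. Cdx2, the master regulator of intestine, had a stronger peak, and Pdx1, Nkx2-1 and Nkx2-5, which direct pancreas and antrum, lung and thyroid, and heart, were marked as well. Barx1, the transcription factor of stomach mesenchyme, had no peak within 1 kb of an annotated start in either replicate's list. The authors' peak value, read as fold enrichment, was 4.26 at Sox2 (chromosome 3, 34650957 to 34651455, inside the gene), 4.56 at Gata4, 3.20 at Gata6 and 3.96 at Foxa2. It was 5.46 at Cdx2 (chromosome 5, 147305921 to 147307636), 3.86 at Pdx1, 5.16 at Nkx2-1 and 4.98 at Nkx2-5. In the replicates' own lists Sox2 had 4.12 and 3.64, and Cdx2 had 5.77 in both. Foxf1, a regulator of gut mesenchyme, was marked in replicate 1 at 4.12 but not in replicate 2 or the replicated list. Acta2, the smooth muscle actin, and Actb, the cytoplasmic actin of all cells, had no promoter peak in any of the 4 lists. In total 2229 of 21938 protein-coding genes (10.2%) had a promoter overlapped by a replicated peak, against a mean of 640.1 and at most 691 in 100 shuffles of the peaks within chromosomes. Replicate 1 alone marked 3248 genes and replicate 2 alone 1849, of which 93.3% were also marked in replicate 1. Of the 2229 genes, 1663 (74.6%) were marked in both replicates' own lists. With only replicated peaks at a q-value of at most 1e-05 the count of marked genes was 956.

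The Hox genes, which set position along the body axis, split by paralogue group. All 16 posterior genes (groups 9 to 13) were marked in the replicated list and in each replicate, as were 9 of 11 central genes (groups 5 to 8) and 6 of 12 anterior genes (groups 1 to 4). Hoxb13, Hoxd12, Hoxa10 and Hoxd11 led the posterior group by covered bases, with folds of 4.76, 5.61, 5.91 and 5.46, and Hoxa13 and Hoxd13 had 3.81 and 3.35. The unmarked genes were Hoxa1, Hoxa2, Hoxa4, Hoxa5, Hoxb2, Hoxb4, Hoxb5 and Hoxc4; of these, Hoxa5 and Hoxc4 had a peak in replicate 1 and none in replicate 2. In the HoxA cluster a block of 53 peaks began at position 52208665 of chromosome 6, 4.08 kb from the unmarked start of Hoxa5, and ran over Hoxa6 to Hoxa13. In the HoxB cluster the block over Hoxb6 and Hoxb7 ended at position 96300761 of chromosome 11, 2.58 kb short of the start of Hoxb5. All 9 genes of HoxD were marked, and 8 of 9 in HoxC. Against all other protein-coding genes the adjusted p of Fisher's exact test was 1.26e-15 for the posterior, 1.18e-07 for the central and 0.000830 for the anterior group. The share of marked genes differed between the anterior and posterior groups (adjusted p = 0.00654, Fisher's exact test) but passed no threshold between the central group and the anterior (0.257) or posterior group (0.251). These belong to a family of 8 pairs of lists chosen after the counts were seen. Neighbouring Hox genes share peaks and are not independent, and with 1 gene kept per cluster the anterior list no longer passed (1 of 4 marked, log2 ratio 0.73 against 1.92, adjusted p = 0.396, exact test). Hoxa3 was marked at its most upstream annotated start, which lies inside the HoxA block. Hoxb3 was marked only through a start other than its 5'-most one, by a peak at 96344544 to 96344845. The 5'-most start of Hoxc5 (102967443) lies beside that of Hoxc10 (102966796), and that of Hoxd4 (74711929) beside that of Hoxd3 (74711927). A single peak there can mark both genes of a pair.

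**Figure D1:**
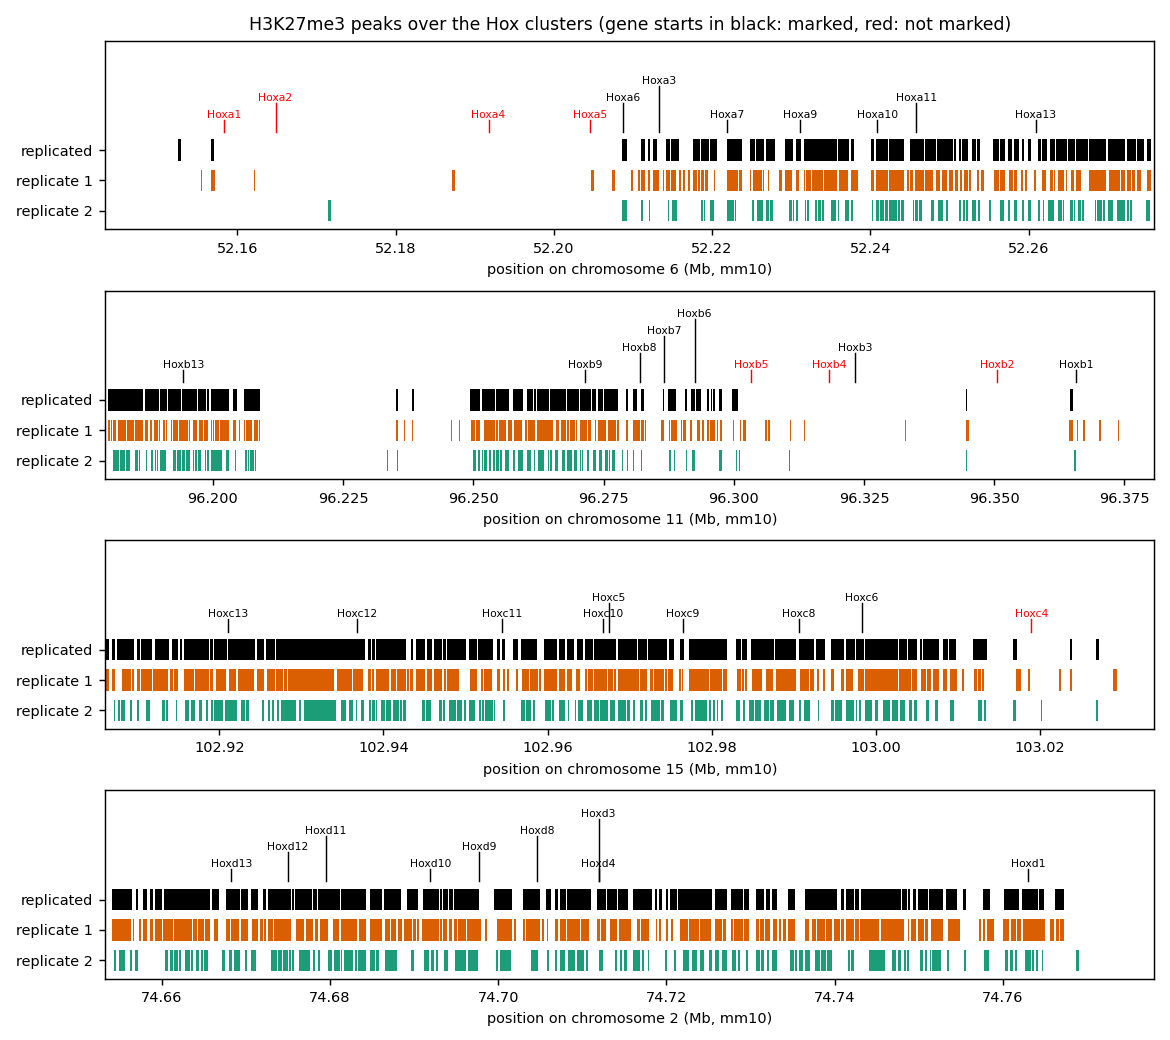
Peaks over the 4 Hox clusters in the replicated list (black) and in replicates 1 (orange) and 2 (green), each box drawn from peak start to end against position in Mb (mm10). Lines above give the 5'-most start of each Hox gene, black if the gene is marked at any annotated start and red if not; the dense HoxA block begins between Hoxa5 and Hoxa6, and all 9 HoxD starts are black.

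Transcription factors of stomach and foregut epithelium were marked in 13 of 21 cases, and those of stomach mesenchyme in 6 of 24. The lists group genes only, and no peak was assigned to epithelial or mesenchymal cells. Besides the genes above, Ovol1 and Onecut2 had folds of 4.37 and 3.98, whereas Ehf and Elf3, regulators of differentiated epithelium, had no promoter peak in any list and Grhl1 had one in replicate 1 and in the pooled list. The marked mesenchymal genes were Hand1 (3.57), Nkx3-2 (4.86), Hlx (4.26), Six2 (3.35), Isl1 and Hand2, the last unmarked in replicate 2. Barx1, Foxf1 and Foxf2 had no replicated peak within 1 kb of a start and counted as unmarked. Replicated peaks did cover 359, 1025 and 1062 bases within 2.5 kb of a start of these genes. The pooled list marked all of them, and replicate 1 marked Foxf1 and Foxf2. The epithelial list passed against all other genes (adjusted p = 2.66e-08) and the mesenchymal one narrowly (0.0367), by Fisher's exact test. The difference between these lists also passed (adjusted p = 0.0343, exact test), yet replicate 1 alone marked 13 mesenchymal genes against 5 in replicate 2, and in replicate 1 the difference between the lists did not pass (0.543). The mesenchymal call (log2 ratio of observed to expected 1.15) ended against genes matched for promoter CpG content (0.90, adjusted p = 0.156, permutation test by random draws). It also ended at similar ratios with only each gene's 5'-most start (1.10, 0.0643), with the stricter q-value (1.18, 0.112) and in replicate 2 alone (1.13, 0.0562), where fewer of its members were marked. Smooth muscle genes were marked in 4 of 18 cases (adjusted p = 0.114, exact test): Ckm, Des, Cnn1 and Mylk, with folds between 2.21 and 4.12. Des was unmarked in replicate 2, and the peak at Ckm, a creatine kinase gene of skeletal and cardiac muscle, had a −log10 q-value of 0.631. Acta2, Actg2 and Cald1 were unmarked. Products of mature stomach epithelium were marked in 5 of 25 (adjusted p = 0.114, exact test): the adhesion genes Cdh1 (4.11) and Epcam (2.69), the keratin Krt19 (3.28), the hormone gene Sst (3.32) and the proton pump gene Atp4a. Agr2, Atp4b and Chia1 had no promoter peak in any list. Of these 5, Krt19, Sst and Atp4a were unmarked in replicate 2.

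Regulators of neighbouring gut organs were marked as well. Intestine and hindgut factors were marked in 8 of 12 cases, led by Cdx2, Evx1 (6.06), Nr5a2 (3.34) and Pitx2 (4.56), with Creb3l3, Hnf4g and Isx unmarked. Factors of lung, thyroid, thymus and pharynx were marked in 13 of 16, led by Tbx1 (5.61), Pax1 (5.61), Pax9 (5.76) and Nkx2-1; the exceptions were Foxn1, Gcm2 and Tbx2. Pancreatic and enteroendocrine factors were marked in 17 of 21, led by Neurod1 (6.06), Neurog3 (6.06), Pax6 (5.61) and Fev (5.76). Bhlha15, Mafb, Myt1 and St18 were not marked. The adjusted p of Fisher's exact test was 6.80e-06, 1.85e-10 and 3.40e-13 for these lists. Neither the intestinal nor the pancreatic share could be told from that of the stomach epithelial list (adjusted p = 1 and 0.349, exact tests).

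Regulators of organs outside the gut were marked to differing extents. Of 66 transcription factors that pattern the central nervous system, 65 were marked, with Neurod6 the exception; replicate 1 marked 65 and replicate 2 64. Lhx3 had a fold of 7.12 (chromosome 2, 26198874 to 26208221), Lhx2 6.22, Gsx1 5.16 and Lhx1 5.91. The list's adjusted p was 2.95e-62 (Fisher's exact test), and its share exceeded that of the stomach epithelial list (adjusted p = 0.000214, exact test). Urogenital factors were marked in 14 of 16 (Tfap2c 5.31, Foxl2 5.16, Emx2 4.41; Hnf1a and Sry unmarked) and limb and axial mesoderm factors in 22 of 27 (Dlx4 5.31, T 3.97, Hoxa11 3.97, Tbx15 5.74). Skeletal and cardiac muscle regulators were marked in 8 of 15, with Irx4 at 6.06, Pax3 at 4.71 and Tbx20 at 4.26, and with Hey2 and Mef2c unmarked; Msc had a peak in each replicate but not in the replicated list. Genes of enteric neural crest, a lineage that populates the gut wall, were marked in 13 of 20, among them Sox10 (5.91), Phox2b (5.13), Tlx2 (5.03), Tubb3 (6.93) and Ascl1 (5.01). Ednrb and Gfra1 had a peak in replicate 1 and none in replicate 2, and Elavl4 had none in either. Blood genes were marked in 8 of 20 (Gata2 5.46, Gfi1 5.15, Tal1 4.76; Cd3e and Csf1r unmarked) and endothelial genes in 7 of 16 (Sox18 6.67, Flt1 3.98, Sox7 4.26; Cdh5, Emcn and Eng unmarked). All of these lists passed, with adjusted p between 2.95e-62 and 0.000810 (Fisher's exact test). Mesothelial genes did not (3 of 10, Wt1, Rspo1 and Lrrn4, adjusted p = 0.0854, exact test; Lrrn4 unmarked in replicate 2), nor did liver genes (0 of 15, among them Alb and Afp, 0.411) or germ cell genes (1 of 24, Pou5f1, unmarked in replicate 2, 0.519). The mesothelial list passed with replicate 1 alone (5 of 10, 0.0119) and where at least 500 covered bases were required (3 of 10, 0.0409), by Fisher's exact test. With replicate 1 alone the smooth muscle list had 6 of 18 marked and passed (0.0463, exact test).

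Families of homeobox and other transcription factors were marked in large part, and some in full. All 12 LIM homeobox and all 9 Pax genes were marked; Pax7 had a fold of 5.91 and Lmx1b 5.73. The mark covered 13 of 14 Nkx genes (Nkx1-1 6.82, Nkx1-2 5.16), and Nkx6-3, a gene of the stomach antrum, was marked in the pooled list only; replicate 1 marked 13 and replicate 2 11 of the 14. Iroquois and sine oculis homeobox genes were marked in 10 of 12 (Six3 6.22; Six4 and Six5 unmarked), GATA genes in 5 of 6 (Gata1 unmarked), T-box genes in 11 of 17, Sox genes in 10 of 19 (Sox1 5.24; Sox11, Sox12 and Sox13 unmarked) and forkhead genes in 22 of 44 (Foxb1 6.08, Foxd4 6.97). Adjusted p ran from 6.08e-12 to 9.34e-05 over these lists (Fisher's exact test). Some genes stand in several lists, so the lists are not independent.

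Genes for secreted signals were also marked. Wnt ligands were marked in 13 of 19, with Wnt7b at 5.15, Wnt6 at 6.06, Wnt3a at 5.12 and Wnt10b at 7.12; Wnt2b, Wnt4 and Wnt5a had peaks in replicate 1 and the pooled list only. Fibroblast growth factors were marked in 11 of 22 (Fgf3 5.76, Fgf8 4.71, Fgf4 4.76; Fgf1, Fgf10 and Fgf13 unmarked), and bone morphogenetic proteins, their antagonists and hedgehogs in 12 of 21. Shh, a ligand made by the gut epithelium, had a fold of 5.01 and Ihh 4.71, while Bmp2 was unmarked and Bmp4 was marked in each replicate but not in the replicated list. Adjusted p was 5.65e-09, 5.27e-06 and 2.95e-07 (Fisher's exact test). Pluripotency genes were marked in 9 of 14 (Fgf4, Esrrb 3.58, Utf1 4.24; adjusted p = 2.76e-06, exact test), with Nanog marked in replicate 2 but not in replicate 1 or the replicated list. Cyclin-dependent kinase inhibitors were marked in 3 of 7: Cdkn2a (5.10), Cdkn2b (5.01) and Cdkn2c (3.81), with Cdkn1a marked in replicate 1 and not in replicate 2 (adjusted p = 0.0354, exact test). That call ended with 1 gene per cluster (log2 ratio 1.17, adjusted p = 0.137) and with the 5'-most start only (1.18, 0.132), by Fisher's exact test. Against CpG-matched genes the ratio stayed at 1.53 and the adjusted p was 0.0646 (permutation test). Imprinted genes were marked in 8 of 28 (Ascl2 3.13, Grb10 4.41, Slc22a3 5.91, Phlda2 4.11; adjusted p = 0.00741, exact test), with Cdkn1c, Dcn and Igf2r unmarked; the log2 ratio of 1.35 fell to 0.87 in replicate 1 alone (adjusted p = 0.0644) and to 1.03 with the stricter q-value (0.150). Of 30 genes for Polycomb complex subunits 4 were marked, Cbx7 (5.01), Cbx8 (3.71), Pcgf5 (3.23) and Kdm2b (3.71), a share that passed no threshold (adjusted p = 0.540, exact test). Replicate 1 alone marked 7 of these 30 genes and replicate 2 alone 4.

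Olfactory and vomeronasal receptor genes, genes with Zfp symbols and housekeeping genes were depleted of the mark. A single olfactory receptor gene of 1092, Olfr94, was marked (adjusted p = 3.47e-49), and 0 of 326 vomeronasal receptor genes (8.25e-15), by Fisher's exact test. Replicate 1 alone marked 10 olfactory and 1 vomeronasal receptor genes, and replicate 2 alone 1 and 0. Genes with Zfp symbols were marked in 8 of 365 (1.22e-08), with Zfp316 at 4.98 and Zfp853 at 3.81. Of 60 genes used in every cell only Rpl3 was marked, by a peak at 80091933 to 80092865 of chromosome 15 that lies upstream of its start (adjusted p = 0.0367, exact test). Actb, Aldoa and Atp5b had no promoter peak in any list. The housekeeping call ended under 6 of the 14 alternative settings, where fewer genes were marked in all and the log2 ratio lay between -2.64 and -1.73, against -2.14. Clustered protocadherins were marked in 1 of 56 (Pcdhac2, adjusted p = 0.0503) and keratins in 3 of 53 (Krt87, Krt19 and Krt1, 0.394), by Fisher's exact test. The protocadherins passed as depleted under 7 of the 14 alternative settings, with adjusted p from 0.00234 against CpG-matched genes to 0.0487 with a q-value of at most 0.05. So did the keratins in replicate 2 alone (0.0274) and with promoters marked in both replicates' own lists (0.0263), where 0 of 53 were marked in each case (exact test). In all, 29 of 41 lists were enriched and 4 depleted.

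**Figure D2:**
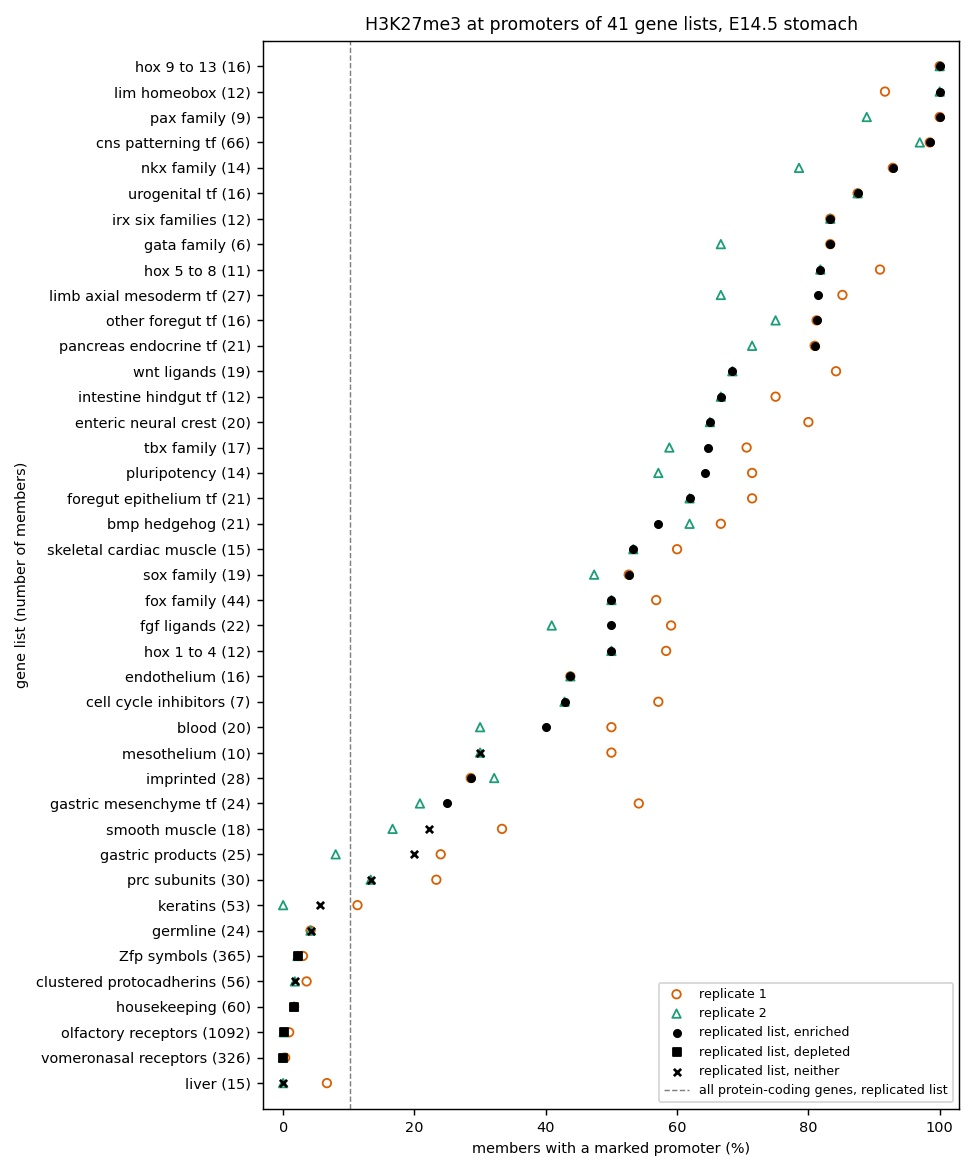
Share of each gene list's members with a marked promoter, in percent, for 41 lists with the number of members in brackets. Black symbols give the replicated list (circle enriched, square depleted, cross neither, Fisher's exact test adjusted over the 41 lists), open orange circles replicate 1 and open green triangles replicate 2; the dashed line is the 10.2% of all protein-coding genes, and posterior Hox, LIM homeobox and Pax genes reach 100%.

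The 3 longest domains of replicated peaks lay over Hox clusters. The first, 121.5 kb with 83 peaks on chromosome 2 (74645778 to 74767295), ran from Evx2 through HoxD to Hoxd1, and the next was 110.4 kb over HoxC from Hoxc13 to Hoxc6. They were followed by HoxA (71.9 kb), Zic1 and Zic4 (71.2 kb), Pax2 (48.3 kb), Tfap2a (46.6 kb), Hoxb13 (44.7 kb), Zic5 and Zic2 (43.9 kb), and Cdkn2a with Cdkn2b (43.3 kb). Dlx6 and Dlx5, Lhx2, Pax6, Pax3 and Tbx3 lay in domains of 40.5, 39.5, 36.5, 36.3 and 36.1 kb. A domain of 41.4 kb at 85452726 to 85494170 of chromosome 17 held no protein-coding start; the nearest belonged to Six3, 119.4 kb away. Replicate 1 peaks covered 68.7% of the HoxD domain and replicate 2 peaks 41.3%. Joining peaks with gaps of at most 3 kb gave 3841 domains with a median span of 1516 bp. Of these, 2256 held no protein-coding start, and 274 spanned at least 10 kb and held 42.0% of all peak bases. The ranking depends on the gap: with gaps of at most 1 kb, and likewise 10 kb, 6 of the 15 longest domains stayed among the 15 longest. HoxC then came first (78.8 and 131.8 kb) and HoxD next (43.7 and 121.5 kb), followed by Zic4 with 1 kb (42.6 kb) and HoxA with 10 kb (118.0 kb).

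Promoters held 4272 of 11612 replicated peaks, or 36.8% (95% Wilson interval 35.9 to 37.7%), against 5.41% on average after shuffling and at most 5.76%. Exons outside promoters took 10.7% (6.20% shuffled), introns 18.1% (31.6%) and sequence between genes 34.4% (56.8%). Genes with intermediate CpG content at their 5'-most start were marked most often. The share was 1.28% in the lowest decile of the CpG observed to expected ratio and 7.89% in decile 10. It was 18.7% in decile 5 and 19.8% in decile 6. CpG content was measured at the 5'-most start only, where 1887 of the 2229 genes marked at any start had a peak. Both replicates peaked in deciles 5 and 6, at 26.9 and 26.7% in replicate 1 and 15.2 and 16.4% in replicate 2. Genes in the upper 5 deciles made up 63.9% of the marked genes. The promoter share was 20.9% in replicate 1 alone, and 55.4% with windows of 2.5 kb to each side.

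**Figure D3:**
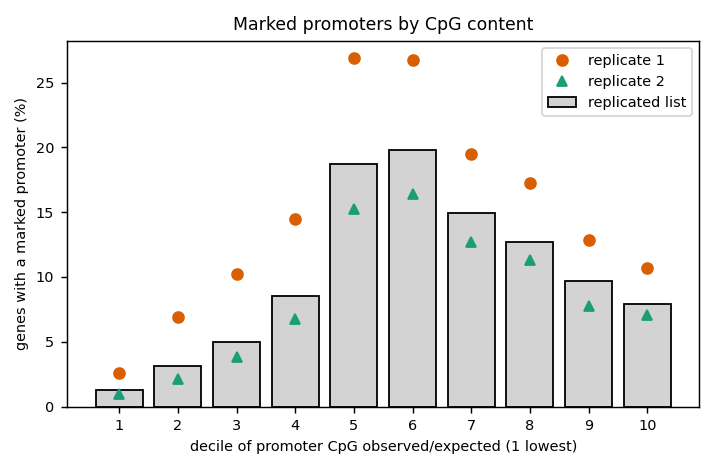
Share of protein-coding genes with a marked promoter, in percent, by decile of the CpG observed to expected ratio within 500 bp of the 5'-most start (1 is lowest). Grey bars give the replicated list, orange circles replicate 1 and green triangles replicate 2; the bars rise from 1.28% in decile 1 to 19.8% in decile 6 and fall to 7.89% in decile 10.

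As raw shares of replicate 2, marked genes were shared with replicate 1 more often (93.3%) than individual peaks (78.4%). The chance levels of genes and peaks differ, and these shares were not tested against each other. Of the genes, 1725 were marked in both, 1523 in replicate 1 only and 124 in replicate 2 only, where independent marking would give 273.8 shared. Of replicate 2 peaks, 9262 (78.4%, interval 77.6 to 79.1%) overlapped a replicate 1 peak by at least 1 base, against 1.02% after shuffling. In the other direction 8160 of 35297 replicate 1 peaks (23.1%, 22.7 to 23.6%) overlapped a replicate 2 peak, against 0.328%. Replicate 1 peaks that overlapped had a median fold of 3.84, and the 27137 that did not had 3.02. Across the 9262 overlapping pairs the folds of the replicates had a Spearman correlation of 0.252; peaks are not independent replicates, and no p-value was computed. The lists differ in length, and with the longer cut to the shorter by p-value the shares were 60.1% and 46.9%. The replicated list held exactly 11612 of the 22931 pooled peaks (50.6%), with a median width of 543 bp against 238 bp for the rest and a median fold of 3.50 against 2.75. Of these, 6457 (55.6%) touched a peak of each replicate and 5155 did not.

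The X chromosome held few replicated peaks and set the replicates apart. In the replicated list the bases covered per Mb of the X were 0.165 of the median autosome (3.34 kb per Mb), and below the lowest autosome (1.70). In replicate 1 the X had 2158 peaks and 3.41 kb per Mb, 0.717 of the autosomal median. In replicate 2 it had 124 peaks and 0.178 kb per Mb, 0.105 of the median. Replicate 1 thus had 17.4 times as many X peaks as replicate 2, while on the 19 autosomes the ratio lay between 2.41 and 3.64. With replicate 1 cut to the length of replicate 2 by p-value, a comparison chosen after these counts were seen, 397 X peaks remained. That was 3.20 times as many as in replicate 2, against 0.887 to 1.14 on the autosomes. Of 948 X-linked protein-coding genes, 119 were marked in replicate 1, 20 in replicate 2 and 33 in the replicated list. The Y chromosome had 0 peaks in all 4 lists. With 1 peak list per biological replicate, and the 2 technical replicates of replicate 1 combined, this difference has no further replicate check.

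**Figure D4:**
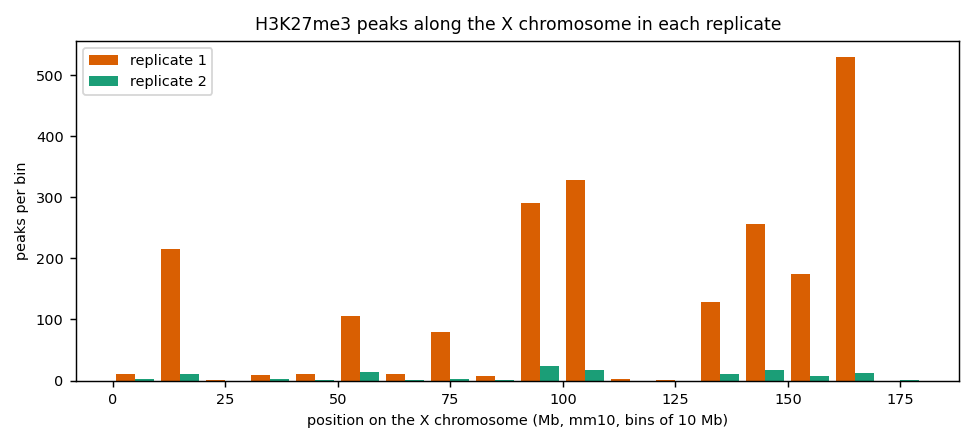
Number of peaks per 10 Mb bin along the X chromosome (mm10) in replicate 1 (orange bars) and replicate 2 (green bars). Replicate 1 reaches 530 peaks between 160 and 170 Mb, where replicate 2 has 12.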

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

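All tests in this part were chosen after the peak lists had been examined. Of the 11319 pooled peaks outside the replicated list, which enter the gene comparisons only where the pooled list is tried in place of the replicated one, 2644 lay at a promoter, or 23.4% (interval 22.6 to 24.1%). What drew attention is the high promoter share among the peaks that the replicated list leaves out: shuffled peaks gave 4.44% on average and at most 4.96%. Shuffles place peaks without regard to sequence, so this does not separate the mark from chance calls that favour promoters. These peaks marked 779 protein-coding genes beyond the 2229, among them Barx1 and Foxf1.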

How the results depend on the processing

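Of the 29 enriched lists, 25 stayed enriched under all 14 alternative settings that included them, and 160 of 230 named genes kept their state under all 11 settings of peaks and windows. The settings added after the data were seen were autosomes only, a q-value of at most 0.05 and promoters marked in both replicates; they moved no count of genes or lists by over 1.5 times. No paired analysis was possible because the series has 1 group of 2 libraries. The cause of the shifts below was not tested, except where the setting itself asks for more overlap or fewer peaks. Requiring overlap of 50% of the peak's own length lowered the shared share of replicate 2 peaks from 78.4 to 66.7% and of replicate 1 peaks from 23.1 to 13.8%; 50% of both lengths gave 27.1 and 9.09%, a q-value of at most 1e-05 59.1 and 10.6%, equal list lengths 60.1 and 46.9%, and autosomes only 24.5% for replicate 1. The rank correlation was 0.355 for pairs sharing 50% of both lengths. The stricter q-value left 956 marked genes. The promoter share of peaks was 26.3% with windows of 500 bp, 55.4% with 2.5 kb, 30.2% in the pooled list and 42.0% with the stricter q-value, and 20.9 to 34.7% leaving out either replicate. The number of domains was 7571 in the pooled list and 3362 to 17119 leaving out either replicate. The X to autosome ratio was 0.371 in the pooled list and 0.105 to 0.717 leaving out either replicate. Marked genes in the upper 5 CpG deciles were 60.9% with windows of 250 bp. The direction turned for mature stomach products (log2 ratio -0.0844 with the 5'-most start, -0.0836 with the stricter q-value, -0.0606 without replicate 1, but 0.63 in the same direction as the main 0.86 without replicate 2) and for Polycomb subunits (-0.30 with the 5'-most start, -0.27 with the stricter q-value), neither of which passed in any setting. Depth limits weak peaks most, and could not be measured from these lists.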

Other observations

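The tests of gene families and of the peaks with the smallest p-values, and the genes named with them, were chosen after their results were seen. The tests of the X chromosome and of replicate 1 peaks were chosen after those patterns were seen and before their own outcomes. Outside the 41 lists, 236 families of at least 10 genes with the same symbol stem were tested in the same way, and 15 were enriched and 3 depleted. A mark at any annotated start counted, so genes with many starts had more chances to be marked. The setting with the 5'-most start only was not tried on families. Tandem-pore potassium channels (Kcnk) were marked in 10 of 14, with Kcnk9 at a fold of 6.82 and Kcnk15 at 6.22, and calcium channel subunits (Cacna) in 9 of 14. Synaptotagmins (Syt), which trigger vesicle release, were marked in 9 of 17, genes with the stem Pde, mostly phosphodiesterases, in 10 of 26, and inward rectifier potassium channels (Kcnj) in 7 of 15, with Kcnj12 at 6.67. Their adjusted p was 1.85e-05, 0.000167, 0.00102, 0.00779 and 0.0134 (Fisher's exact test), and these 5 also passed against CpG-matched genes. Serotonin receptors (Htr, 7 of 14, 0.00941) and sodium channels (Scn, 6 of 14, 0.0295) passed by the exact test but not against CpG-matched genes (0.0515 and 0.113). The same held for the stems Galnt, Prdm, Gpr, Rgs, Adcy, Sema, Car and Cdh, with adjusted p between 0.0289 and 0.0470 (exact test). Some of these counts moved with the replicate: Rgs had 8 marked, but 11 in replicate 1 and 4 in replicate 2, and Adcy 5, but 6 and 2. Others moved less, such as Prdm with 6 marked (6 and 5) and Cdh with 7 (9 and 8). Histone genes (0 of 67) and Wdr genes (0 of 64) were depleted (0.0295 for each, exact test), also against CpG-matched genes. Neighbouring genes of a family are not independent, and the setting with 1 gene per cluster was not tried on families. Keratin-associated protein genes (Krtap, 0 of 57, 0.0470) were not depleted against CpG-matched genes (0.701).

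Of the 274 domains of at least 10 kb, 37 held no protein-coding start, and 26 of these lay within 50 kb of one. After the domain near Six3, the longest was 32.6 kb on chromosome 7 (79525186 to 79557832), with the marked Rhcg nearest at 37.1 kb. A domain of 29.4 kb on chromosome 13 (83712717 to 83742124) lay 59.8 kb from the start of Mef2c, which was itself unmarked.

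Replicate 1 had 2158 peaks on the X and replicate 2 had 124. Both sets were unevenly placed. The 5 bins of 10 Mb with the most replicate 1 peaks, picked on these same counts, held 1619 of them. The same bins held 66.1% of the replicate 2 peaks and 28.8% of the X-linked protein-coding genes. Replicate 1 had 530 peaks between 160 and 170 Mb and 1 between 120 and 130 Mb. The shorter list of replicate 2 could account for a part only: with replicate 1 cut to the same length the ratio on the X fell from 17.4 to 3.20 (interval 2.62 to 3.92), still above the highest autosome (1.14). The share of replicate 1 X peaks that overlapped a replicate 2 peak, 2.09%, decides nothing, since the number of replicate 2 peaks there holds it near 5.75% at most. Different control files, or different shares of female embryos with an inactive X in the pools, could each raise the rest widely over the X; X peaks without a partner lay in introns or between genes in 86.9% of cases (autosomes 77.2%) and at promoters in 7.76% (autosomes 16.4%, shuffled at most 2.93%). These explanations cannot be told apart, since both controls and pools differ with the replicate and the labels give no sex ratio.

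Most replicate 1 peaks, 27137 of 35297, had no overlapping replicate 2 peak. Replicate 2 listed only 11818 peaks, which limits how many replicate 1 peaks can have a partner. With replicate 1 cut to the same length by p-value, 46.9% of its peaks overlapped a replicate 2 peak, against 23.1% uncut. A majority thus still had no partner at equal length, and list length could account for a part only. Chance calls spread evenly over the chromosomes are unlikely as the whole source. Of the peaks without a partner, 15.7% lay at promoters, against at most 4.66% in shuffles. Shuffles place peaks without regard to sequence, so they cannot decide on chance calls that favour promoters. Within 3 kb of a replicate 2 peak lay 31.8% (interval 31.2 to 32.3%) of the peaks without a partner, above the 1.26% of shuffles. That is under the 50% predicted if broad domains called in different pieces were the source. Replicate 2 peaks covered only 41.3% of the longest domain, over HoxD, so pieces of a domain may lie over 3 kb from any of them. The share therefore sets no upper limit on what such domains account for. A difference in depth between the libraries stays open, and no biological explanation was tested.

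The 4 replicated peaks with the smallest p-values were not at promoters of developmental genes. Ranks 1 and 3 lay on chromosome 17 at 39843033 to 39846788 and 39847880 to 39848911, over an annotated ribosomal RNA gene, with folds of 2.40 and 2.03. Rank 2 lay in Cdk8 (4.83) and rank 4 at 36231109 to 36231669 of chromosome 17 outside any gene (5.09), both high folds within the list (percentiles 89.4 and 93.0). Reads from repeated copies collapsed onto 1 place stay open as a source: the highest fold of the 4, 5.09, was below the lowest of the next 16 (6.64), but this difference is what drew attention to them and decides nothing. No biological explanation was tested.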
